A study of Mus musculus with 6 samples.

How the data were processed

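RNA had been prepared from the tibial and femoral bone marrow of 3-week-old wild-type mice and mice without functional Cbx2 (Cbx2-/-), with 3 animals per genotype, per the labels. Per the labels' protocols, the libraries were stranded and poly(A)-based, and were read as 50-base single-end reads on a HiSeq 1000. FastQC 0.11.5, TopHat2 2.1.0, Cufflinks 2.2.1 and the mouse build mm10 are named per the submitters' processing notes, which give no roles, settings or gene annotation. The deposited table gives an FPKM value (fragments scaled to transcript length and to all mapped fragments) for 22838 genes in each of 6 libraries, and the authors deposited no read counts in the table used here. Its lower and upper confidence limits were equal to each other in every row and differed from the FPKM in 21 to 26 rows of a library, so they gave no interval and were not used. A status other than OK stood at 8 gene and library pairs, in 6 genes.

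FPKM is a relative measure: a transcript's value falls when other transcripts take a larger share of the reads. The summed FPKM of a library ranged from 599601 to 741192. Total reads are not given in the sources used here. The commonest ratio of values under 0.15 FPKM between libraries, which approximates the ratio of what 1 read is worth, put the depths of the other libraries at 0.91 to 1.21 times that of wild-type replicate 1. This estimate came from 695 to 981 genes per library and is approximate, because Cufflinks assigns fractions of reads. The strand setting of the quantification is not given in the sources used here, so values of overlapping and antisense genes, and of near-identical paralogs, are uncertain.

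Values were analysed as log2(FPKM + 1), so a difference on this scale understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 12006 genes. The genotypes were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. The fit used no block and no covariate. All folds are ratios of mean FPKM, and spreads of FPKM are SD over 3 libraries, while an SE is named as such. On simulated data with the gene spreads of this comparison, 200 of 12006 genes were changed. The fit recovered 71% of genes changed by 1 log2 unit and 99% of genes changed by 2 log2 units, and 11 of its 181 calls were false. The simulated noise was independent between genes and of equal spread in both groups. The real libraries do not have these properties, so these rates do not describe the calls reported below.

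Before the data were examined, 45 gene lists of cell types, pathways and complexes were fixed, together with the test, the alternatives and the rule for naming genes. The lists hold 893 distinct genes, of which 692 were tested. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 45 lists, with camera at an estimated correlation and fry beside it. Counts of list members past the threshold are given over all tested genes and adjusted over the list alone. Genes are named by the rule when they are Cbx2, among the 10 largest rises or falls past the threshold with separate groups and a mean of at least 2 FPKM, or among the 4 members of a list with the lowest adjusted p. In the osteoblast, adipocyte, adipogenic transcription factor and Wnt lists, up to 4 members that did not pass are named too, by mean FPKM. Unnamed gene models, small RNAs and receptor gene segments were left out. Genes named outside the rule are said to be so. Apart from the rule, Xist and the Y-linked genes were fixed beforehand to be read in every library, since the labels do not give the sex. The rule gave Cbx2 and 162 other genes, of which 142 passed the threshold.

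Gene positions are from GENCODE vM21 (GRCm38, the assembly of mm10), counted from 1. Of 21683 symbols with a GENCODE gene of their own, 99.3% overlapped the locus in the deposited table. Each library was left out in turn, and other pseudocounts, filters, scalings and limma settings were tried, as was the replicate number as a block. Covariates for chromosomal sex and for skeletal muscle transcripts, and a fit leaving out 2 libraries with muscle transcripts, were added after the data were seen. The fallback fixed for a table with pooled values was not needed. Figures were drawn with matplotlib 3.10.9.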

Results

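Bone marrow transcripts were measured by RNA sequencing in 3 wild-type mice and 3 Cbx2-/- mice at 3 weeks of age. Cbx2 encodes a chromodomain protein of Polycomb repressive complex 1, which keeps developmental genes silent. The mean body weight was 12.3 g in the wild-type group and 4.0 g in the Cbx2-/- group, per the labels. The series title sets the question of how Cbx2 acts on osteoblastic and adipogenic differentiation in long bones after birth. Between 16140 and 16574 genes had a value above 0 in a library. The correlation of log2 values was 0.986 to 0.989 between wild-type libraries, 0.946 to 0.987 between Cbx2-/- libraries and 0.91 to 0.953 between the genotypes. The labels do not give the sex of the animals. Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to 31.1 FPKM in wild-type replicate 1 and to 31.1 FPKM in Cbx2-/- replicate 1, with Xist at 0.015 and 0.462 FPKM. The other 4 libraries had Xist between 11.5 and 24.5 FPKM and summed Y-linked transcripts of at most 0.087 FPKM, so the genotypes had the same mix of both patterns.

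Cbx2 (chromosome 11, 119022962 to 119031270, plus strand) was read first as the targeted gene. Its FPKM was 2.90, 3.83 and 2.75 in the wild-type libraries and 2.11, 1.87 and 1.88 in the Cbx2-/- libraries. The difference of -0.49 ± 0.15 (log2, SE) had a limma adjusted p of 0.0558. An exact permutation test, two-sided, gave p = 0.1, the smallest that 3 against 3 libraries allow. The labels do not describe the allele, so these values do not show which part of the transcript was read. Of the 21 tested members of Polycomb repressive complex 1, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.682, fry adjusted p = 0.0347). Cbx6, a paralog of Cbx2, fell from 14.3 ± 1.08 to 5.39 ± 0.681 FPKM (SD, n = 3 each). Bmi1, a core subunit, rose from 5.68 ± 0.329 to 8.89 ± 0.726 FPKM, a call lost in 4 of the 6 fits that left out 1 library. In Polycomb repressive complex 2, 1 of 11 members fell (1 adjusted over the list alone, camera adjusted p = 0.374, fry adjusted p = 0.0368). This was the methyltransferase gene Ezh2, at 57.7 ± 1.59 and 29.9 ± 7.11 FPKM, whose call was lost in 3 of those fits.

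Among 12006 tested genes, 1057 were higher and 998 lower in Cbx2-/- marrow (limma, adjusted p under 0.05). Differences of at least 1 log2 unit were found for 308 of the higher and 492 of the lower genes. The groups did not overlap in 4756 genes, 39.6% of those tested, where chance gives 10%. The largest rises held 5 stefin A family genes on chromosome 16 (Stfa1, Stfa2, Stfa3, Stfa2l1 and BC100530) and 5 genes of fat cells (Retn, Cidec, Adig, Cfd and Fabp4). The largest falls held genes of B cell precursors (Igll1, Vpreb1, Vpreb3 and Dntt), Fcrla and Fam129c (both in none of the fixed lists), both osteocalcin genes (Bglap and Bglap2), the myosin light chain gene Myl4 and the secreted matrix protein gene Cthrc1. The libraries left out mattered to these counts: without Cbx2-/- replicate 3, 2069 genes were higher and 1719 lower. Leaving out wild-type replicate 1, 2 or 3 gave 374, 391 and 367 higher and 475, 478 and 542 lower genes, and leaving out Cbx2-/- replicate 1 gave 543 and 551.

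Osteoblast genes fell together. Bglap (chromosome 3, 88383501 to 88384464), which encodes the bone matrix hormone osteocalcin, fell from 1255 ± 242 to 91.5 ± 33.9 FPKM (SD, n = 3 each), 13.7-fold lower, by 3.81 ± 0.29 on the log2 scale (SE, limma adjusted p = 0.000459). Its neighbour Bglap2 fell from 619 ± 145 to 43.9 ± 18.2 FPKM. These 2 genes are near-identical, so how reads were divided between them is uncertain. Col11a2, a fibrillar collagen chain gene, fell 9.68-fold, and Ifitm5, an osteoblast membrane protein gene, fell 6.34-fold. Of the 22 osteoblast genes, 15 fell, 0 rose and 7 did not pass (18 fell adjusted over the list alone), with a median difference of -1.53. The list was called by camera (adjusted p = 9.07e-12), with an adjusted p = 0.33 with an estimated correlation.

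The other osteoblast genes did not pass, including some with separate groups. Spp1, the gene of the matrix protein osteopontin, was at 522 ± 98.7 FPKM in wild-type and 1001 ± 582 FPKM in Cbx2-/- marrow (limma adjusted p = 0.225). Ibsp, the bone sialoprotein gene, was at 59.8 ± 6.4 and 26.8 ± 16.2 FPKM (limma adjusted p = 0.0551). Cdh11, an adhesion gene of mesenchymal cells, was at 15 ± 3.31 and 15.8 ± 4.99 FPKM. Omd was at 9.49 ± 2.59 and 4.29 ± 2.55 FPKM. Runx2, the transcription factor gene at the head of the lineage, named outside the rule after its values were seen, was at 5.31 ± 0.184 and 4.44 ± 0.122 FPKM (limma adjusted p = 0.24).

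Adipocyte genes rose. Adig, a gene expressed during fat cell formation, rose from 0.503 ± 0.252 to 15.7 ± 3.85 FPKM (SD, n = 3 each). Cidec (chromosome 6, 113424634 to 113435760), a lipid droplet protein gene, rose 17.3-fold, by 3.51 ± 0.25 on the log2 scale (SE, limma adjusted p = 0.000343). Cfd, which encodes the secreted protease adipsin, rose from 29.5 ± 4.39 to 331 ± 105 FPKM, and Retn, the resistin gene, from 1.49 ± 1.05 to 38.9 ± 21.7 FPKM. Fabp4, a fatty acid carrier gene also expressed in endothelium, rose from 252 ± 96.8 to 1870.4 ± 240.7 FPKM, and Pck1 rose from 0.603 ± 0.461 to 10.1 ± 0.101 FPKM. Of the 19 tested adipocyte genes, 13 rose, 0 fell and 6 did not pass (14 rose adjusted over the list alone), with a median difference of 1.12. The list was called by camera (adjusted p = 3.6e-10), with an adjusted p = 0.208 with an estimated correlation.

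The adipocyte genes that did not pass included Adipoq, the adiponectin gene, at 49.6 ± 12.7 and 67.3 ± 23.3 FPKM (limma adjusted p = 0.347). Scd1 was at 17.6 ± 0.727 and 33.5 ± 22.6 FPKM, Thrsp at 5.95 ± 2.05 and 11.3 ± 5.08 FPKM, and Car3 at 93.9 ± 32.5 and 117 ± 139 FPKM. Among 13 adipogenic transcription factors, 4 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.358 with an estimated correlation). Pparg (chromosome 6, 115360951 to 115490399), the nuclear receptor gene required for fat cell formation, rose from 9.72 ± 0.067 to 20.8 ± 2.74 FPKM. Cebpa rose 1.91-fold and Rxra 1.7-fold, with the calls lost in 1 and 3 of the 6 fits that left out 1 library. Ebf1, which also acts in B cell precursors, fell 2.43-fold. Cebpb, Srebf1, Stat5a and Nr3c1 did not pass, with differences of 0.50, 0.28, 0.35 and 0.01 (log2).

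**Figure D1:**
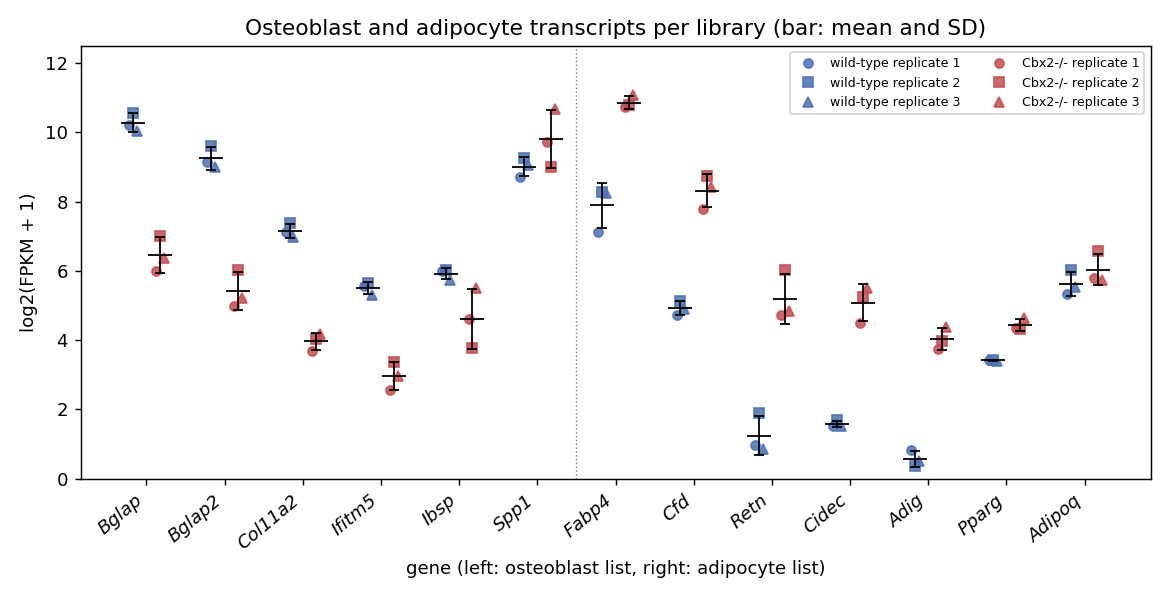
Each point is the log2(FPKM + 1) of 1 library for a gene of the osteoblast list (left of the dotted line) or the adipocyte list (right), in wild-type (blue) and Cbx2-/- (red) marrow, and bars give the mean and SD of 3 libraries. Bglap, Bglap2, Col11a2 and Ifitm5 lie lower and Fabp4, Cfd, Retn, Cidec, Adig and Pparg higher in each Cbx2-/- library than in any wild-type library, while the points of Spp1 and Adipoq overlap.

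Skeletal muscle transcripts differed between the Cbx2-/- libraries. Acta1 was at 79.1 and 133 FPKM in Cbx2-/- replicates 1 and 2 and at 1.89 FPKM in replicate 3, and Ckm was at 73.5, 50.8 and 0.46 FPKM. The wild-type means were 1.06 FPKM for Acta1 and 0.897 FPKM for Ckm. These muscle genes were named outside the rule after their values were seen. None of the 7 tested muscle genes passed limma's adjusted p (0 also adjusted over the list alone), although camera called the list (adjusted p = 0.0257, median 2.73), with an adjusted p = 0.54 with an estimated correlation. Without Cbx2-/- replicate 3, 7 rose, and with replicates 1 and 2 left out, 0 rose and 1 fell. With both muscle-bearing libraries left out, 14 adipocyte genes rose and 1 fell, and 14 osteoblast genes fell and 1 rose, in a fit where the lone Cbx2-/- library is assumed to vary like the others.

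Many endothelial and marrow stromal genes rose, while some fibroblast and matrix genes fell. Of 18 endothelial genes, 10 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 5.58e-09, adjusted p = 0.143 with an estimated correlation). Stab2, a scavenger receptor of sinusoidal vessels, rose from 5.76 ± 0.066 to 19.4 ± 0.984 FPKM (SD, n = 3 each), and the vascular growth factor receptor gene Kdr rose 2.76-fold. Of 15 marrow stromal genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 8.05e-05, adjusted p = 0.33 with an estimated correlation). Bmp4, a growth factor gene, rose 3.37-fold, and Gas6, a ligand gene for TAM receptors, 2.55-fold. Of 24 fibroblast and matrix genes, 1 rose, 8 fell and 15 did not pass (1 and 11 adjusted over the list alone, camera adjusted p = 0.00308, adjusted p = 0.505 with an estimated correlation). With Cbx2-/- replicates 1 and 2 left out, 6 of these rose and 11 fell. Among them, Col5a2 fell 6.48-fold, the proteoglycan genes Lum and Dcn 6.1-fold and 3.59-fold, and Fbln1 3.91-fold.

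The cartilage collagen genes that could be tested were lower too. Col2a1 fell from 24.2 ± 1.06 to 2.37 ± 1.5 FPKM and Col11a1 from 73.5 ± 22.5 to 6.06 ± 2.52 FPKM (SD, n = 3 each), but only 5 chondrocyte genes could be tested, of which 2 fell (2 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0518). That list was called as falling in several other fits, such as those with no filter on low values (camera adjusted p = 0.000364) and with the replicate block (camera adjusted p = 0.0358). With all libraries it had an adjusted p = 0.358 with an estimated correlation and a fry adjusted p = 0.00149. Of 12 osteoclast genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.913). The protease gene Mmp9, also a neutrophil gene, rose 1.71-fold, and Acp5, the tartrate-resistant phosphatase gene, fell 1.75-fold, calls lost in 4 and 5 of the 6 fits that left out 1 library. Of 8 osteocyte genes, 1 fell, Pdpn, by 3.89-fold (1 adjusted over the list alone, camera adjusted p = 0.163). Without Cbx2-/- replicate 3, 5 osteocyte genes fell, but with replicates 1 and 2 left out, 3 rose and 1 fell. The mean log2 level of this list was 3.61 in replicate 3, above the wild-type range of 2.64 to 3.28, and 2.29 and 2.13 in replicates 1 and 2.

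B cell precursor genes showed the largest falls of any list by median. Vpreb1 and Igll1, which encode the surrogate light chain of the pre-B cell receptor, fell from 43.9 ± 7.47 to 0.619 ± 0.404 FPKM and from 71.9 ± 11 to 1.29 ± 0.966 FPKM (SD, n = 3 each). Vpreb3 fell by 4.82 ± 0.30 on the log2 scale (SE, limma adjusted p = 0.000191). Dntt, the terminal transferase that adds bases at rearranging receptor genes, fell 44.5-fold. Of 19 early B cell genes, 17 fell and 0 rose (18 fell and 1 rose adjusted over the list alone), with a median of -2.31. Camera called the list (adjusted p = 1.33e-16), with an adjusted p = 0.147 with an estimated correlation.

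Some genes of mature B cells and plasma cells fell too. Of 18 mature B cell genes, 6 fell (6 adjusted over the list alone, camera adjusted p = 0.000429, adjusted p = 0.505 with an estimated correlation), among them Spib, a transcription factor gene, which fell from 100.5 ± 13.9 to 10 ± 4.04 FPKM, and Cd72, which fell 10.8-fold. Without Cbx2-/- replicate 3, 12 fell, and with replicates 1 and 2 left out, 5 fell and 1 rose. Of 6 plasma cell genes, 3 fell (3 adjusted over the list alone, camera adjusted p = 0.0257, adjusted p = 0.463 with an estimated correlation): Irf4, Pou2af1 and Mzb1, by 11.9-fold, 8.78-fold and 8.43-fold. Pou2af1 is also in the early B cell list, and the other tested plasma cell genes did not pass. These falls do not show a change of plasma cells separate from that of B cell precursors. None of 10 T cell genes passed limma's adjusted p (0 adjusted over the list alone, camera adjusted p = 0.102). The T cell list was called as rising with the replicate block (camera adjusted p = 0.0226) and with no filter on low values (camera adjusted p = 0.0375), and 7 of its genes rose with Cbx2-/- replicates 1 and 2 left out. With all libraries it had an adjusted p = 0.672 with an estimated correlation, and its mean log2 level was 0.88 above wild-type in replicate 3 and 0.13 above in the other replicates. Of 6 NK cell genes, Klre1 and Gzma fell, 5.41-fold and 1.54-fold (2 adjusted over the list alone, camera adjusted p = 0.0846), the call of Gzma being lost in 5 of the 6 fits that left out 1 library. Of 11 dendritic cell genes, 3 fell (3 adjusted over the list alone, camera adjusted p = 0.147, fry adjusted p = 0.0347), with Ly6d at 289 ± 60.5 and 36.2 ± 7.82 FPKM. Klk1 fell 26-fold from a low level and Siglech 3.01-fold, the call of Siglech being lost in 3 of the 6 fits that left out 1 library. Which cells these transcripts came from was not tested.

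Erythroid genes fell. Trim10, expressed in maturing red cell precursors, fell from 186 ± 33.6 to 40.9 ± 8.21 FPKM (SD, n = 3 each). Kel, a blood group gene, fell 3.08-fold, and Epb4.2, the protein 4.2 gene, 3.88-fold. Of 26 erythroid genes, 18 fell and 0 rose (20 and 0 adjusted over the list alone), with a median of -1.44. Camera called the list (adjusted p = 1.85e-13), with an adjusted p = 0.147 with an estimated correlation. The tested globin genes of the list (Hba-a1, Hbb-b1, Hbb-b2 and Hbb-bs, named outside the rule after their values were seen) did not pass, with a limma adjusted p of 0.137 to 0.693. Their values are uncertain because globin paralogs are close in sequence, and Hba-a2 was under the filter. Haemoglobin transcripts took 17.8%, 14.7% and 13.9% of the summed FPKM in the wild-type libraries and 10.9%, 7.02% and 20.5% in the Cbx2-/- libraries.

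Stefin A genes, among the largest rises, lay side by side on chromosome 16. Stfa3 (chromosome 16, 36450537 to 36455392), a stefin A cysteine protease inhibitor gene, rose from 15.6 ± 5.92 to 517 ± 103 FPKM (SD, n = 3 each), 33.1-fold higher (limma adjusted p = 0.000166). Stfa2 rose 33.8-fold, BC100530 19.7-fold, Stfa1 15.3-fold and Stfa2l1 from 55.2 ± 9.02 to 552.9 ± 80.6 FPKM. These paralogs are close in sequence, so their separate values are uncertain. In this stretch, examined after its values were seen, all 9 tested genes from Stfa2l1 to Stfa3 rose, 6.31-fold to 33.8-fold. The nearest tested genes on either side, Ccdc58 and Cd86, did not pass (limma adjusted p = 0.789 and 0.124). Beyond Cd86, Slc15a2 was 3.28-fold higher and Eaf2 2.82-fold lower (limma adjusted p = 0.0138 and 0.0124). These flanking genes were named outside the rule after their values were seen. The labels give a mixed strain, and whether the groups differed in strain DNA at this stretch was not tested. The stefin A genes are in none of the fixed lists.

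Neutrophil and macrophage genes rose. Of 21 genes of maturing neutrophils, 12 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 1.69e-07, adjusted p = 0.143 with an estimated correlation). Chil3, a chitinase-like protein gene, rose from 689.6 ± 7.67 to 2338 ± 820 FPKM. Without Cbx2-/- replicate 3, 20 rose, and with replicates 1 and 2 left out, 13 rose. Of 12 primary granule genes of promyelocytes, 5 rose (8 adjusted over the list alone, camera adjusted p = 0.000957, adjusted p = 0.5 with an estimated correlation), including the granule protease gene Ctsg, 2.79-fold, a call lost in 2 of the 6 fits that left out 1 library. Without Cbx2-/- replicate 3, 10 rose, but with replicates 1 and 2 left out, 4 rose and 3 fell. The mean log2 level of the promyelocyte list was 7.50 in replicate 3, 8.23 and 8.25 in replicates 1 and 2, and 7.18 to 7.33 in wild-type libraries.

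Of 18 macrophage genes, 10 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 1.65e-05, adjusted p = 0.358 with an estimated correlation). Cd5l rose 3.86-fold and Hmox1, the haem-degrading oxygenase gene, 2.46-fold. Of 14 monocyte genes, 5 rose (6 adjusted over the list alone, camera adjusted p = 0.14). Eosinophil, basophil and mast cell genes went the other way, with 1 of 14 rising and 6 falling (1 and 7 adjusted over the list alone, camera adjusted p = 0.0257, adjusted p = 0.39 with an estimated correlation). Ear1, an eosinophil ribonuclease gene, fell 3.1-fold, and Prg2, the major basic protein gene, fell from 1048 ± 195 to 391 ± 99.5 FPKM, a call lost without wild-type replicate 3 (limma adjusted p = 0.0562). Of 18 megakaryocyte genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.239), although the list median was -0.259 (log2). The 2 were Nbeal2, 1.78-fold, and Selp, 1.92-fold, calls lost in 3 and 4 of the 6 fits that left out 1 library. Of 17 stem and progenitor genes, 2 rose and 3 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.723). Kit and Gata2 rose 2.04-fold and 1.85-fold, and Sox4 fell 3.7-fold.

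**Figure D2:**
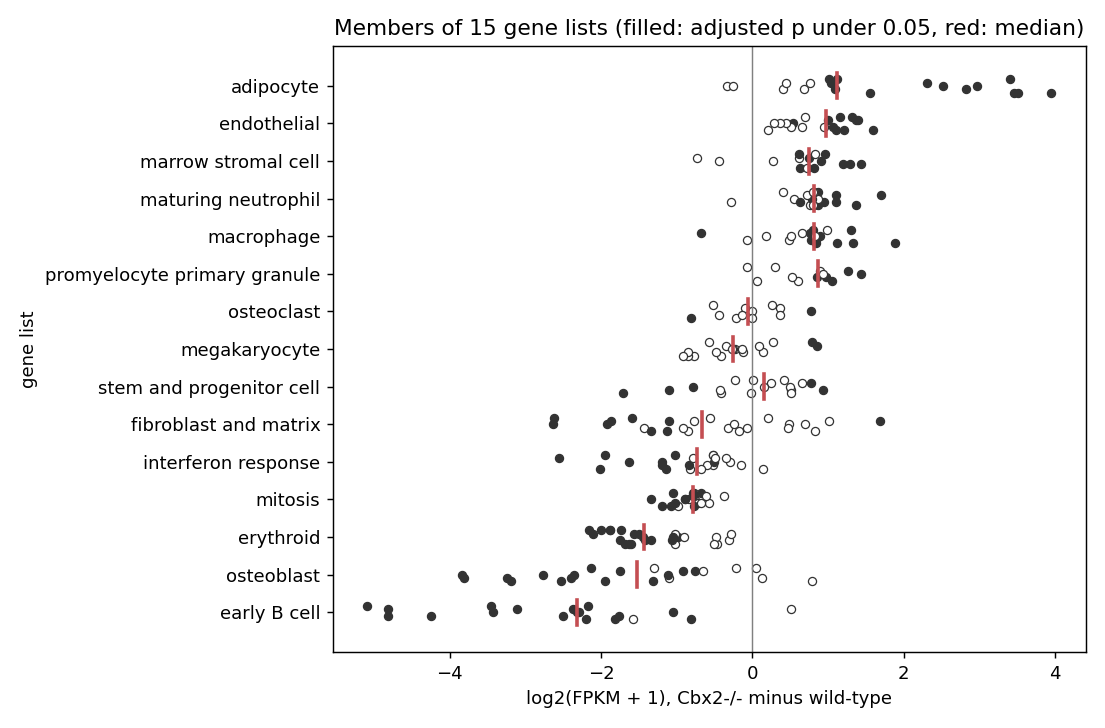
Each point is a tested member of 1 of 15 gene lists at its log2(FPKM + 1) difference, Cbx2-/- minus wild-type, filled where the limma adjusted p is under 0.05, and red lines give list medians. The adipocyte median lies at 1.12 and the osteoblast, erythroid and early B cell medians at -1.53, -1.44 and -2.31.

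Some genes of dividing cells fell, most of them in mitosis. Mki67, a marker of cycling cells, fell from 123 ± 7.32 to 59.1 ± 0.236 FPKM and Cenpf, a kinetochore gene, from 11.9 ± 1.11 to 5.31 ± 0.233 FPKM (SD, n = 3 each). Of 20 mitosis genes, 11 fell and 0 rose (14 and 0 adjusted over the list alone, camera adjusted p = 1.67e-08, adjusted p = 0.463 with an estimated correlation). With Cbx2-/- replicates 1 and 2 left out, 20 mitosis genes fell, and without replicate 3, 14 fell. The mean log2 level of the mitosis list lay -1.35 from wild-type in replicate 3 and -0.58 in the other replicates. Of 21 DNA replication genes, only Ccne2 fell, 2.62-fold (1 adjusted over the list alone), a call lost in 2 of the 6 fits that left out 1 library, although camera called the list (adjusted p = 1.34e-05, median -0.81), with an adjusted p = 0.505 with an estimated correlation. Without Cbx2-/- replicate 3, 9 DNA replication genes fell, and with replicates 1 and 2 left out, 20 fell. Of 22 p53 targets and cell cycle inhibitors, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.85): Perp, 2.23-fold, and Cdkn2c and Cdkn2d, 1.99-fold and 1.68-fold, all lost in at least 4 of those fits.

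**Figure D3:**
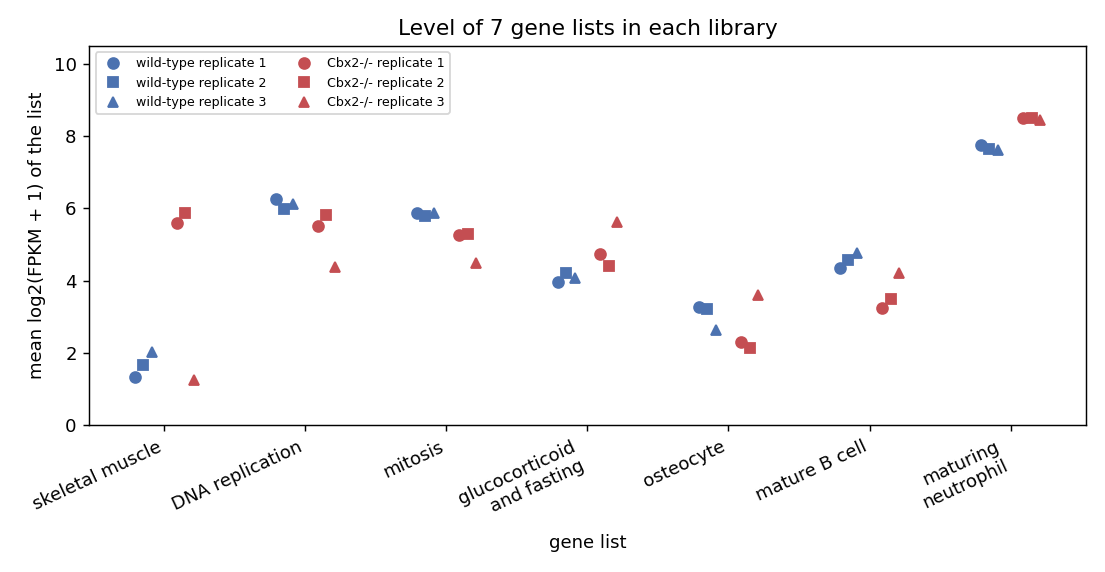
Each point is the mean log2(FPKM + 1) of a list's tested members in 1 library, for 7 lists, in wild-type (blue) and Cbx2-/- (red) marrow. Cbx2-/- replicate 3 lies at 1.25 in the muscle list, where replicates 1 and 2 lie at 5.59 and 5.87, and at 4.38 in the DNA replication list, where they lie at 5.52 and 5.83.

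Among developmental genes that Polycomb complexes silence in many tissues, most were below the level tested. Of 6 tested Hox genes, Hoxb2 fell 2.16-fold (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.913), a call lost in 5 of the 6 fits that left out 1 library. The other 33 Hox genes of the list were under the filter. With no filter on low values, a fit fixed before the data were examined, camera called the Hox list as rising (adjusted p = 0.03, median 0.11), with an adjusted p = 0.469 with an estimated correlation. In that fit, 3 Hox genes rose and 1 fell. Hoxb6 was at 0.316 and 0.78 FPKM (means of wild-type and Cbx2-/-), Hoxb9 at 0.186 and 0.69, and Hoxd9 at 0.0868 and 0.376, with a limma adjusted p of 0.0159, 0.0127 and 0.0441, all named outside the rule after their values were seen. Of 10 tested developmental transcription factor genes, 2 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.0091, adjusted p = 0.505 with an estimated correlation). Twist1 fell 3.96-fold, and Tbx2 fell 1.94-fold, a call lost in 3 of the 6 fits that left out 1 library. With no filter on low values, this list was not called (camera adjusted p = 0.0592), and its median was -0.0159. The other 42 genes of the list were under the filter. Its falling call thus rests on members with measurable transcript and does not show that silenced genes fell.

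Wnt and BMP pathway genes, which act in bone formation, moved both ways. Of 12 tested Wnt ligand and receptor genes, 3 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0846, fry adjusted p = 0.018). The receptor genes Fzd1, Fzd4 and Fzd7 rose 4.89-fold, 3.5-fold and 1.71-fold, and the ligand gene Wnt5b fell 1.99-fold, the calls of Fzd7 and Wnt5b each being lost in 5 of the 6 fits that left out 1 library. Lrp5, Ryk, Lrp4 and Lrp6 did not pass, with differences of 0.40, -0.13, 0.39 and 0.15 (log2). The other 22 genes of this list were under the filter. Among them, the ligand gene Wnt10a was at 1.56 ± 0.545 FPKM in wild-type and 0.0691 ± 0.0676 FPKM in Cbx2-/- marrow. The receptor gene Fzd6 went the other way, at 0.5 ± 0.143 and 0.866 ± 0.0534 FPKM. Both were named outside the rule after their values were seen. With no filter on low values, the list was not called (camera adjusted p = 0.649, median 0.0235). Of 14 Wnt antagonists and feedback targets, 6 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.0091, adjusted p = 0.5 with an estimated correlation). The secreted antagonist gene Sfrp4 fell 3.95-fold, and Lgr5, a receptor gene and Wnt target, fell from 1.57 ± 0.301 to 0.0618 ± 0.0366 FPKM. Lef1, also expressed in B cell precursors, fell 3.9-fold. The list was not called with FPKM at least 5 in 3 libraries (camera adjusted p = 0.149) or without Cbx2-/- replicate 2 (camera adjusted p = 0.0561). Its mean log2 level in Cbx2-/- replicate 3, 2.56, lay within the wild-type range of 2.51 to 2.73, while replicates 1 and 2 were at 1.81 and 1.85. Sost, Wisp2, Tcf7 and Apcdd1 did not pass, and Sost was at 9.31, 8.95 and 49.8 FPKM in the 3 Cbx2-/- libraries. Of 15 BMP genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.181), with the target gene Id2 2.7-fold and the antagonist gene Fst 6.14-fold higher.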

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

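The chromosomal sex covariate, the muscle score covariate and the fit leaving out both Cbx2-/- libraries with muscle transcripts were chosen after seeing the data. Under the other pseudocounts, filters, scalings and limma without trend or robust, 771 to 1089 genes were higher and 755 to 1105 lower, within 1.5 times the main counts. Library weights gave 3278 higher and 2684 lower genes, the muscle score covariate 2127 and 2649, and leaving out both libraries with muscle transcripts 2047 and 2714. Requiring a difference of at least 1 on the log2(FPKM + 1) scale left 308 and 492. Leaving out each library in turn gave 367 to 2069 higher and 475 to 1719 lower genes, and 287 higher and 415 lower genes were called in all 6 such fits, as were 88 of the 142 named genes past the threshold. The causes were not tested.

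Same-numbered libraries had deviation correlations of 0.194, -0.179 and -0.103, and only Cbx2-/- replicate 1 correlated best with its own number. With so few libraries, this does not settle whether the numbers pair the samples, and the labels do not say. With the replicate block, 634 genes were higher and 734 lower.

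The osteoblast and adipocyte lists kept their direction and their call under every alternative, with medians of -1.95 to -1.20 and 0.96 to 1.34, except with an estimated correlation, where the medians were -1.53 and 1.12 and neither was called (adjusted p = 0.33 and 0.208). Then 0 lists rose and 0 fell, against 11 and 14. Without 1 library, 11 to 14 lists rose and 13 to 17 fell. With the muscle score covariate, and leaving out both libraries with muscle transcripts, the fibroblast, skeletal muscle, mature B, plasma, promyelocyte, eosinophil, developmental factor, Wnt antagonist and fetal growth lists were not called, while the oxidative phosphorylation and ribosomal protein lists fell. The plasma list was not called with no filter on low values, nor the adipogenic factors with library weights, nor the amino acid stress list with library weights or without wild-type replicate 1, Cbx2-/- replicate 2 or 3. Besides oxidative phosphorylation and ribosomal protein genes, lists not called in the fit of all libraries were called in at least 1 alternative for chondrocyte, osteocyte, NK, megakaryocyte and dendritic genes (falling) and Hox, T cell, monocyte, immediate early, BMP, Wnt ligand, growth hormone and NF-kB genes (rising). By fry, 8 of the 11 and 7 of the 14 had an adjusted p under 0.05. Of all 45 lists, 20 did so by fry. The others were the chondrocyte, Wnt ligand, dendritic and both Polycomb complex lists, which camera did not call (fry adjusted p = 0.00149 to 0.0368). Cbx2 passed with quantile normalization (-0.52), library weights (-0.42) and without Cbx2-/- replicate 3 (-0.47); over the fits without 1 library it was -0.56 to -0.37, and it was not tested at 5 FPKM in 3 libraries. Adjusted p of Cbx2 ranged from 0.0106 to 0.194.

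Of 3379 values of named genes under alternatives, 3094 kept direction and side of the threshold, 241 lost the call, 27 gained it and 17 changed sign, in genes that had not passed. Nr3c1 was -0.0153 with median-of-ratios scaling and -0.0898 with library weights, where Cdh11 was -0.31. With the muscle score covariate, Sost was 1.19 and passed (limma adjusted p = 0.0321), and Apcdd1 was 0.20; leaving out both libraries with muscle transcripts gave 1.33 and 0.32, where neither passed. Without 1 library, values ranged over both signs for Sost (-1.0003 to 0.18; 0.16 and 0.15 without wild-type replicate 1 and Cbx2-/- replicate 1), Cdh11 (-0.17 to 0.26; -0.0979 without wild-type replicate 3), Nr3c1 (-0.0977 to 0.0646; -0.0344 without wild-type replicate 3), Apcdd1 (-0.57 to 0.0464), Car3 (-1.30 to 0.33) and Lrp6 (-0.0121 to 0.32). Total reads are unknown, so how far depth limited genes with low values is not known.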

Other observations

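Some interferon-stimulated genes fell in Cbx2-/- marrow: Isg15 fell 5.83-fold, Usp18 5.29-fold, Rsad2 4.23-fold and Oas3 3.8-fold. Of 22 tested genes of this list, 10 fell, 0 rose and 12 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 5.58e-09, adjusted p = 0.275 with an estimated correlation). In the growth axis, Ghr, the growth hormone receptor gene, rose 5.84-fold and Igf2 4.33-fold; of 18 such genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0821), with 10 rising when Cbx2-/- replicates 1 and 2 were left out and 6 without replicate 3. Of 12 fetal and neonatal growth genes, 4 rose (5 adjusted over the list alone, camera adjusted p = 0.00731, adjusted p = 0.402 with an estimated correlation), with the imprinted cell cycle inhibitor gene Cdkn1c 2.86-fold higher.

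Of 17 glucocorticoid and fasting response genes, 3 rose (3 adjusted over the list alone, camera adjusted p = 0.00111, adjusted p = 0.505 with an estimated correlation): Angptl4, Txnip and Sgk1, by 3.32-fold, 2.23-fold and 2.24-fold, each lost in 3 of the 6 fits that left out 1 library. With Cbx2-/- replicates 1 and 2 left out, 15 rose, and without replicate 3, 6 rose. Of 17 hypoxia and glycolysis genes, 5 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.00135, adjusted p = 0.178 with an estimated correlation), with the oxygen-sensing hydroxylase gene Egln3 2.51-fold higher. Of 18 cholesterol synthesis genes, 6 fell (7 adjusted over the list alone, camera adjusted p = 0.00111, adjusted p = 0.505 with an estimated correlation), with Fdft1 2.05-fold lower. Of 16 amino acid and ER stress genes, 3 fell (4 adjusted over the list alone, camera adjusted p = 0.0257, adjusted p = 0.522 with an estimated correlation), with Ddit3 1.82-fold lower. This list was not called with library weights or without wild-type replicate 1, Cbx2-/- replicate 2 or Cbx2-/- replicate 3, and 10 of its genes fell with Cbx2-/- replicates 1 and 2 left out. Of 15 immediate early genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0545), with Fos 3.61-fold higher and Btg2 2.66-fold lower. Of 12 inflammatory and NF-kB genes, 2 rose, Tnf and Socs3, by 2.48-fold and 2.45-fold (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.19). With all 6 libraries, none of 30 oxidative phosphorylation genes and 39 ribosomal protein genes passed limma's adjusted p (0 adjusted over the list alone in either, camera adjusted p = 0.155 and 0.964), where 3900 genes had an unadjusted p under 0.05. These lists depended on Cbx2-/- replicate 3: with replicates 1 and 2 left out, 26 oxidative phosphorylation genes and 12 ribosomal protein genes fell, and without replicate 3, 1 and 3 rose.

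The tests below on body tissue, body size, library depth, list pairs in Cbx2-/- replicate 3 and the genes near Cbx2 were chosen after their values were seen, while for those on other splits, on the muscle covariate and on correlations without muscle genes, what each outcome would mean was written before its result was seen. The covariate itself and the test on correlations were chosen after the muscle transcripts had been seen in the data. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The genotype split gave 1057 higher and 998 lower genes, and the highest count of any other split was 1 in either direction; in each case 1 split, the genotype split itself, reached its count. The direction of another split is arbitrary, so the larger of its counts in the 2 directions was taken. For camera with a preset correlation, 7 of the 10 splits called in this way at least as many lists as the 11 rising lists of the genotype split, with 17 the highest other, and 2 of the 10 reached its 14 falling lists, with 17 the highest other. Each other split still sets 2 libraries of a genotype against 1. Its list calls may hold part of the genotype difference, so the splits do not show how many list calls would arise without it. For genes, the mixing adds the difference between the groups to the spread within each side. Low gene counts in the other splits would thus follow from any strong difference between the groups, whatever its cause. They do not support the genotype counts.

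The osteoblast fall was set against tissue yield. A lower share of non-blood tissue would lower the marrow stromal list as well, but its median was 0.745 (log2), with an SE of its mean of 0.151. The marrow stromal list shares Vcam1 (named outside the rule) with the macrophage list, which rose, so its level does not settle the share of non-blood tissue. A lower yield of bone surface would lower osteoclast genes about as far, but their mean lay 1.61 ± 0.303 (SE) above that of the osteoblast genes. Both SE were taken over list members, which move together, and not over animals, so they understate the uncertainty. By library, the mean log2 level of the osteoclast list was 4.33 to 4.73 in Cbx2-/- and 4.45 to 4.63 in wild-type marrow. The osteoblast list was at 4.22 to 4.77 and 5.94 to 6.43. The osteoclast list shares Mmp9, which rose, with the neutrophil list and Itgb3 with the megakaryocyte list. Its members Calcr and Tnfrsf11a were under the filter. Itgb3, Calcr and Tnfrsf11a are named outside the rule. The level of the osteoclast list thus does not settle how much bone surface was sampled. A lower yield stays open, since Acp5, the fibroblast and matrix list, Col2a1 and Col11a1 were lower too. An effect of the smaller body size of the Cbx2-/- animals cannot be told apart from one of genotype, because the labels give only group mean body weights, of which the genotypes share 0, and fewer osteoblasts against less transcript per osteoblast was not tested.

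The adipocyte rise was set against tissue carried over with skeletal muscle. With the muscle score as a covariate, 14 of 19 members rose, against 13 without it, and the bound set for arguing against this explanation was 7. That bound was too lenient, because only 1 Cbx2-/- library has a muscle score within or below the wild-type range, so the genotype term rests on replicate 3. Fat carried over with muscle cannot be told apart from marrow fat for replicates 1 and 2, and fat carried over without muscle was not tested. Cidea, a member of the adipocyte list under the filter, was named outside the rule after its values were seen. It was at 0.0781, 0.0886 and 5.14 FPKM in Cbx2-/- replicates 1, 2 and 3 and at 0 FPKM in each wild-type library. Carried-over fat stays open for replicate 3 as well.

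Cbx2-/- replicate 3 stood apart from the other Cbx2-/- libraries: its mean correlation with them was 0.951, against 0.987 between them. Muscle transcripts in the other libraries do not account for this, since without 442 genes that follow the muscle score the gap was still 0.0345, above the 0.01 set before. For a shallower library, fewer detected genes were predicted, and 156 more were detected than in the mean of the others. That count also depends on which genes are expressed, so it cannot decide on depth. The depth estimate relative to wild-type replicate 1 was 1.07 in replicate 3, between the 1.19 and 1.02 of Cbx2-/- replicates 1 and 2. A candidate explanation is a stronger glucocorticoid and fasting response with less DNA replication in this animal. The list medians differed from the other replicates by 1.25 and -1.37, a difference of 2.61. The central 95% of 10000 random pairs of lists ran from -0.235 to 0.602. Counting the real pair, the share as large was 0.0001, the smallest that these draws can give. Members of these lists move together (estimated correlation 0.448 and 0.934), which those of random lists need not do. Both lists were picked after their values were seen, so this test overstates the case and stays open, and other lists set this library apart too, with mean log2 levels differing from the other replicates by 1.40 for osteocyte, -0.90 for oxidative phosphorylation, 0.84 for mature B cell and -0.73 for ribosomal protein genes, against 1.05 for the glucocorticoid list.

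Genes near Cbx2 were examined as a sign of strain 129 DNA kept around a targeted locus, which is a hypothesis, since the labels give a mixed 129/C57BL/6 strain and no allele. Within 5 Mb, 30 of 149 genes were called (20.1%, 95% exact binomial interval 14.0% to 27.5%), against 17.1% of 11856 genes elsewhere (Fisher's exact test, one-sided, p = 0.189), a result that leaves open an excess of up to the interval's upper end.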
